A study of Homo sapiens with 9 samples.

How the data were processed

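Poly(A)-selected RNA of ALL-SIL cells was sequenced after electroporation with a TLX1 or NTC siRNA, in 9 libraries of 3 groups with 3 libraries each, per the labels. Per the labels' protocols, cells grew in RPMI with fetal bovine serum, RNA was purified with a column kit, and libraries came from a TruSeq mRNA kit that does not mark strand. What NTC stands for, the siRNA sequences, the dose and the time of harvest are not given in the sources used here.

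The values analysed are deposited counts: whole numbers of reads per gene, 1 table per library, with no normalization, as the deposited values themselves show. Each table opens with 4 summary lines that are not genes, and has 1 count without regard to strand and 2 counts by strand. The layout is that of STAR's per-gene output, but the aligner, its settings and the annotation are not given in the sources used here. The genome build was GRCh38, per the submitters' processing notes. The unstranded count was used, because the kit does not mark strand and the strand counts were close to equal in total (50.2% to 50.6%). Reads of a gene and of an antisense or overlapping partner cannot be told apart in such counts, and genes with near-identical copies are uncertain. Between 75.5% and 77.6% of reads fell in genes. Of 58096 gene identifiers 57492 matched GENCODE release 29 on GRCh38, which gave symbols, positions and biotypes. The 604 unmatched ones held 0.0317% of counts.

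Depth ranged from 58305492 to 99524663 gene counts per library, so counting error is small for genes above a few CPM. No pair of replicates was a repeat of the other: chi-square per degree of freedom over genes lay between 35.3 and 59.3. TLX1 is given in CPM of all gene counts, and the other CPM values are scaled by the normalization factors.

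Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM factors (0.975 to 1.04), filterByExpr by group (minimum count 10, minimum total 15), which kept 18554 genes, and a quasi-likelihood test in 1 fit of all 3 groups, which share 1 estimate of the spread. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors (SE) of log2 fold changes were derived as the absolute log2 fold change over the square root of the test's F statistic. The comparisons were both TLX1 siRNA groups, weighted equally, against NTC, each of them against NTC, siRNA1 against siRNA2, and genes that passed the same way under both. LncRNA genes were taken by biotype (14421 identifiers). Log2 CPM with a prior count of 2 was used for the correlations between libraries, the principal components and the 3′ UTR word search. The list tests used the log2 CPM and weights of limma's voom.

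The 32 gene lists (826 gene names, 1 of them unmatched and 2 matched through another symbol) covered T cell receptor signalling, thymocyte stage markers, NOTCH1 targets, T cell transcription factors, T-ALL tumour suppressors and transcription factor oncogenes, G1/S and G2/M phase genes, spindle checkpoint, interferon-stimulated, p53 target and BCL2 family genes. They also covered ATF4 and the unfolded protein response, cholesterol synthesis, glycolysis and hypoxia, MYC and nucleolar genes, ribosomal proteins, mitochondrially encoded genes, immediate-early genes, NF-kappa-B targets, MHC class I and II, GIMAP genes, JAK-STAT signalling, integrins and migration receptors, and RNA interference machinery. Markers of NK, B, myeloid, erythroid and epithelial cells and a list of lncRNAs completed them. List sizes in the results count only members kept by filterByExpr. It kept 9 of 25 T-ALL transcription factor oncogenes, 7 of 13 MHC class II genes, 9 of 16 B cell, 5 of 17 myeloid and 3 of 16 erythroid markers. The median levels of those kept were 3.95, 0.781, 1.89, 0.232 and 0.158 CPM in this order. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, and with fry, adjusted over the lists of a comparison. The groups, tests, lists, the rule for named genes and all alternatives except those named as later additions were fixed before the data were examined.

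The rule for named genes took TLX1, TLX1NB, TLX2 and TLX3 always; up to 10 genes each way by fold change (5 each way for lncRNAs) that passed in the combined and both single comparisons with a mean CPM of at least 1 (0.5 for lncRNAs); 5 each way by fold change between the siRNA groups; up to 4 members per list that passed in the combined comparison; and the 5 each way with the smallest adjusted p in the combined comparison. The parts that required passing under both siRNA labels named no gene. The same sizes were therefore applied to the siRNA1 comparisons, and genes named this way were chosen after their values were seen, as were genes called only with the replicate block.

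Alternatives were RLE factors and library size alone in place of TMM, no filter beyond 1 count, a CPM of 1 in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, only the groups compared, the sum of the strand counts, a 1.5-fold threshold, an adjusted p under 0.01, and each library left out in turn. Chosen after seeing the data were a fit without the 3 replicate 1 libraries, and for the lists library size alone and the block with an estimated correlation or with fry. To see whether replicate numbers pair the samples, deviations from group means were correlated between libraries: the 9 same-number pairs correlated at 0.383 to 0.623 (median 0.463), other pairs at −0.445 to 0.0693, and 9 of 9 libraries were best matched by one with their own number. The first principal component (31.8% of variance) parted the replicate 1 libraries and the third (16.1%) those labelled siRNA1. Every same-number pair exceeded 0.1, so the numbers were taken to pair the samples, as a result of this check and not of the labels. The unblocked fit, fixed beforehand, stayed the main one, and genes that did not pass in it may pass with the block. The total counts of the blocked fit are given beside the results, with its values for part of the named genes and lists.

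The fit was tested on counts simulated for all 9 libraries and 18554 genes, from real means by replicate number without group effects. The spread came from the blocked fit, so the simulated samples are paired by replicate number. Genes were changed in the libraries labelled siRNA1 and tested against NTC, and the first run is given. The fit without the block recovered 32.8% of 67 genes changed 1.5-fold, 58.2% of 67 changed 2-fold and 86.4% of 66 changed 4-fold. It called 0 unchanged genes. The fit with the block recovered 71.6%, 83.6% and 98.5% and called 11 unchanged genes. It also called 2 genes in the comparison of siRNA2 with NTC, where none was changed. For comparisons that share libraries, 20 simulations of unchanged groups gave the values due to sharing alone.

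Words of 7 bases in 3′ UTRs were searched for a link to lower expression. For 9722 genes and 16061 words, the deviation of each group from the others was adjusted for 3′ UTR length, base composition and expression, and each word's z was set against limits from 100 permutations. The search recovered 3 of 3 words planted in simulated data. Transcripts seen in the libraries of 1 replicate number were listed by a floor of 3 counts. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.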

Results

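Gene expression was measured by polyA+ RNA sequencing in ALL-SIL, a human cell line established from a T-cell acute lymphoblastic leukaemia (T-ALL) that expresses TLX1. TLX1 is a homeobox transcription factor that acts as an oncogene in T-ALL. Cells were electroporated with a small interfering RNA (siRNA), a short duplex RNA that directs cleavage of the mRNA it matches. Per the labels, 3 libraries received TLX1 siRNA1, 3 received TLX1 siRNA2 and 3 received the NTC siRNA, and each group holds replicates 1 to 3. The libraries labelled NTC held 65009361, 99524663 and 83457675 gene counts in replicates 1 to 3. Those labelled siRNA1 held 95072634, 92843482 and 91864795, and those labelled siRNA2 held 71118461, 81903079 and 58305492. The test covered 18554 genes, 3360 of them long noncoding RNA (lncRNA) genes. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. PCR reads without molecular identifiers are not independent molecules, so floors set from counts cover counting error only.

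The targeted gene was measured first, since it checks the labels. TLX1 (ENSG00000107807.12) lies on the plus strand of chromosome 10 from 101130505 to 101137789 (GRCh38, GENCODE 29). TLX1 mRNA stood at 179, 168 and 183 CPM (counts scaled to a common total of gene counts) in replicates 1 to 3 labelled NTC. It stood at 402, 452 and 401 CPM in those labelled siRNA1, and at 198, 225 and 185 CPM in those labelled siRNA2. The means were 176.7 ± 8.15 CPM for the NTC label, 418.2 ± 29.2 CPM for the siRNA1 label and 202.7 ± 20.4 CPM for the siRNA2 label (SD, n = 3 each). TLX1 mRNA was thus 2.34-fold higher in the libraries labelled siRNA1 than in those labelled NTC (log2 fold change 1.23, SE 0.10, edgeR quasi-likelihood adjusted p = 0.000449), and all 3 of the former lay above all 3 of the latter. This goes against the labels, because a TLX1 siRNA is meant to lower this mRNA. TLX1 did not pass the test between the libraries labelled siRNA2 and NTC (log2 fold change 0.19, SE 0.10, edgeR adjusted p = 1, unadjusted p = 0.0923). Between the libraries labelled siRNA1 and siRNA2 it was 2.05-fold higher in the former (log2 fold change 1.04, SE 0.10, edgeR adjusted p = 0.00115). Directions are therefore given by label throughout, and none is read as an effect of lowering TLX1.

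**Figure D1:**
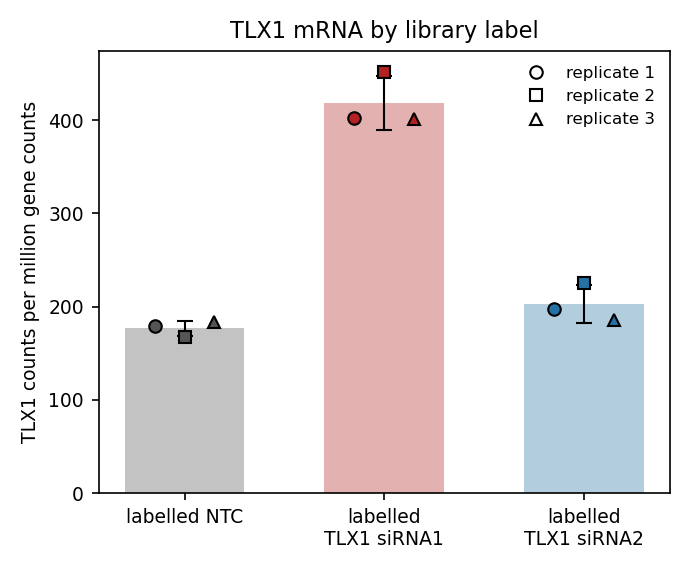
TLX1 level in each of the 9 libraries, in CPM of gene counts (vertical axis, from 0), by labelled group (horizontal axis), where points are libraries and bars give the group mean with its SD (n = 3). The libraries labelled siRNA1 sit between 401 and 452 CPM, above all other libraries, of which the highest stands at 225 CPM.

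The other genes of the family and locus were at or near the floor of detection. TLX1NB, an antisense gene on chromosome 10 from 101089321 to 101131126 that overlaps the start of TLX1, had 0 counts in all 9 libraries, although unstranded counting cannot tell overlapping genes apart. TLX2 (chromosome 2 from 74513463 to 74517147) had at most 5 counts in any library. TLX3 (chromosome 5 from 171309284 to 171312134), another homeobox oncogene of T-ALL, had 33, 54 and 41 counts in the replicate 1 libraries labelled NTC, siRNA1 and siRNA2, and 0 in the other 6 libraries.

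The first single comparison asks which genes differ between cells given TLX1 siRNA1 and cells given NTC siRNA. DAB2IP, TC2N and ADGRG1 were among the lower genes in the libraries labelled siRNA1, and SNAI2, RXRA and CCR4 among the higher ones. DAB2IP, a Ras GTPase-activating protein, was 6.92-fold lower (log2 fold change −2.79, SE 0.20, adjusted p = 0.00015 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment), at 18.7 ± 3.62 CPM under the NTC label and 2.70 ± 0.718 CPM under the siRNA1 label (SD, n = 3 each). ADGRG1, an adhesion G protein-coupled receptor, was 3.43-fold lower (log2 fold change −1.78, SE 0.13, edgeR adjusted p = 0.00015), from 96.4 ± 14.8 to 28.1 ± 4.37 CPM (SD, n = 3 each). TC2N was 5.97-fold lower, and TSHR, the thyrotropin receptor, 3.32-fold lower. TERT, the catalytic subunit of telomerase, was also lower (log2 fold change −1.36, SE 0.22). SNAI2, a zinc-finger repressor of transcription, was 3.93-fold higher (log2 fold change 1.97, SE 0.25), and RXRA, the retinoid X receptor alpha, was 2.76-fold higher. CCR4, a chemokine receptor, was 2.54-fold higher (log2 fold change 1.34, SE 0.14, edgeR adjusted p = 0.0011), from 57.2 ± 7.79 to 145 ± 8.98 CPM (SD, n = 3 each). The interferon-inducible GTPase GBP2 and the kinase MAP3K8 were higher with log2 fold changes of 1.35 and 1.11.

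Further genes past the test with large differences were CXCR3 (1.95), CYB561 (1.89), CHDH (1.60), NCR2 (1.55), HLA-DMB (1.41), LINC002481 (1.27), GOLGA7B (1.26) and GPR65 (1.22) on the higher side, as log2 fold changes. On the lower side were IGLL1 (−1.69), PTPRU (−1.69), DIP2C (−1.47), WNK2 (−1.42), DEFA8P (−1.38) and MZB1 (−0.82). By edgeR quasi-likelihood, 238 genes passed at an adjusted p under 0.05, 87 higher and 151 lower, of which 23 and 26 differed more than 2-fold. With the replicate number as a block, 2117 genes passed (1016 higher, 1101 lower). DAB2IP (ENSG00000136848.16) lies on chromosome 9 from 121567057 to 121785530, ADGRG1 (ENSG00000205336.11) on chromosome 16 from 57610652 to 57665580, and CCR4 on chromosome 3 from 32951574 to 32956349. Of the 54 named genes that passed here, all 54 had all 3 libraries labelled siRNA1 on one side of all 3 labelled NTC. They were chosen for passing on these libraries, so this is no further evidence, and chance gives such a split to 10% of unselected genes. The count fell to 149, 110 and 103 without NTC replicates 1, 2 and 3. It fell to 121, 131 and 125 without siRNA1 replicates 1, 2 and 3, and to 75 without the 3 replicate 1 libraries. Of the 54 named calls, 33 held with any 1 library left out. Of the others 12, 15 and 16 were lost without NTC replicates 1, 2 and 3, 17, 13 and 15 without siRNA1 replicates 1, 2 and 3, and 3, 3 and 2 without siRNA2 replicates 1, 2 and 3. The calls of TLX1, DAB2IP, TC2N, ADGRG1, TSHR, TERT, SNAI2, RXRA, CCR4, GBP2, DIP2C, WNK2 and LINC002481 held in all 19 alternatives that refit the counts. Among the genes listed here edgeR lost PTPRU in 6 of the 9 fits with 1 library left out (highest adjusted p = 0.175), CHDH in 5 (0.175), DEFA8P in 5 (0.081) and NCR2 in 4 (0.1). Of the 126 lower genes whose 3′ UTR was searched, 42 (33.3%) held the 7-base word GCAGTAC there, against 4.12% of the other genes searched, and of the 64 higher genes 3 held it. The word was found by a search of the same libraries, so these counts describe it and do not test it.

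Among the lists fixed before the data were examined, some NOTCH1 targets and thymocyte markers fell in the libraries labelled siRNA1 and some cytotoxic cell markers rose. Without the replicate block most members did not pass. Of 14 NOTCH1 targets, 2 fell and 12 did not pass: IL7R, the interleukin-7 receptor alpha chain (log2 fold change −1.33, SE 0.14, edgeR adjusted p = 0.00134), and the receptor NOTCH3 (−0.79, SE 0.10, edgeR adjusted p = 0.00285). Adjusted over the list alone, 5 fell, and with the replicate block 8 fell. The camera test, which ranks a list against all other genes, placed the list low (adjusted p = 1.43e-05; adjusted p = 0.109 with an estimated correlation), as did fry, which tests the list's own direction (adjusted p = 0.0105). Of 25 thymocyte stage markers, 3 fell. They were IL7R, DNTT, the terminal transferase of antigen receptor rearrangement (−1.34, SE 0.22), and ARPP21 (−0.89). Adjusted over the list alone 9 fell and 1 rose, and with the block 14 fell and 4 rose (camera adjusted p = 0.000256; adjusted p = 0.418 with an estimated correlation; fry adjusted p = 0.152, and 0.00473 with the block). Of 23 NK and cytotoxic cell markers named, 12 were tested, with a median of 0.714 CPM. Among these 12, 2 rose, the interleukin-2 receptor beta chain IL2RB (0.71) and the granule protein gene NKG7 (0.56). Adjusted over the list alone 2 rose, and with the block 4 (camera adjusted p = 0.00127; adjusted p = 0.117 with an estimated correlation; fry adjusted p = 0.0105). These markers are also expressed by T cells, and the list speaks of no other cell by itself.

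Single members of the next lists fell. Of 34 MYC and nucleolar genes, 1 fell, ODC1, the first enzyme of polyamine synthesis (log2 fold change −0.57), with 2 adjusted over the list alone and 10 under the block (camera adjusted p = 1.43e-05; adjusted p = 0.56 with an estimated correlation). Of 43 G1/S phase genes, 1 fell, UHRF1 (−0.50), a factor in the maintenance of DNA methylation, with 1 adjusted over the list alone, and under the block 5 lower and 1 higher (camera adjusted p = 0.0476; adjusted p = 0.717 with an estimated correlation). The G1/S call was lost without NTC replicate 1, where the direction turned (camera adjusted p = 0.859), NTC replicate 3 (0.268), siRNA1 replicates 2 (0.831) and 3 (0.0919), and siRNA2 replicate 3 (0.0535). Of 9 transcription factor oncogenes of T-ALL, 1 fell, MYB (−0.53), with 1 adjusted over the list alone and 2 under the block (camera adjusted p = 0.0626; fry adjusted p = 0.03). In all, camera called 5 of 32 lists (1 up, 4 down), none with an estimated correlation, and fry called 3. With the block camera called 13 and fry 9. Without NTC replicate 2 or siRNA1 replicate 1 camera called 9 lists, without siRNA2 replicate 2 it called 8, and without the 3 replicate 1 libraries 8.

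**Figure D2:**
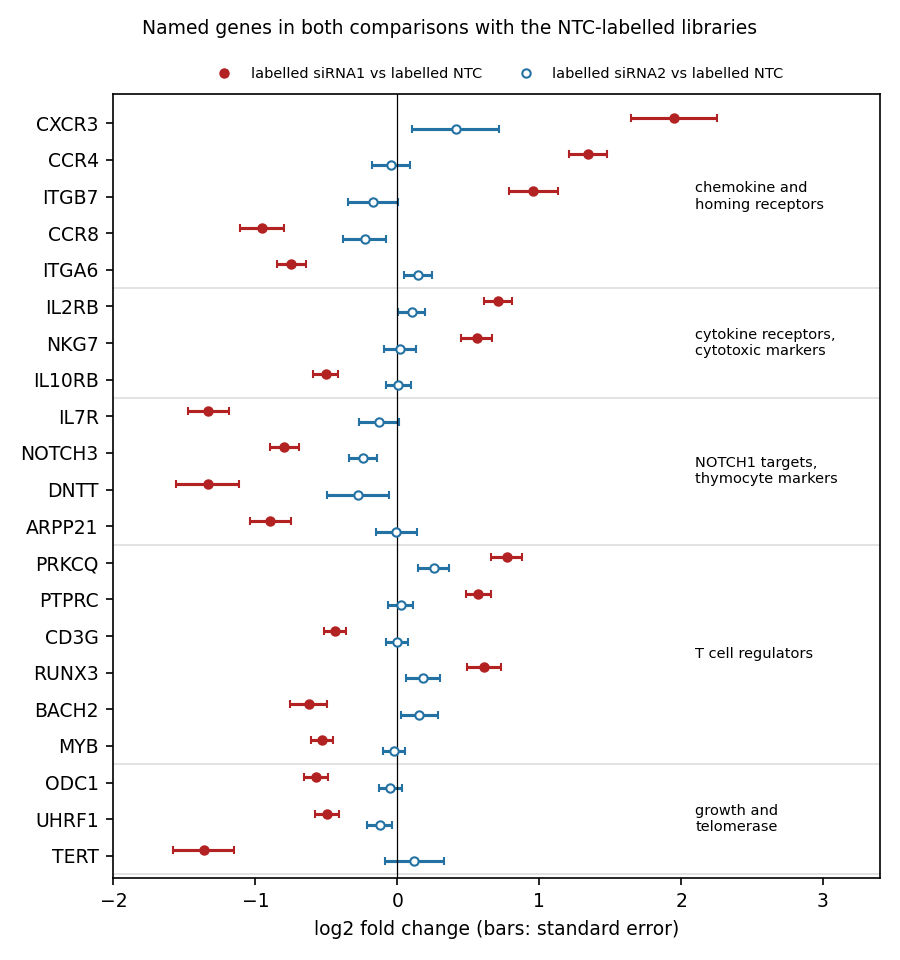
Log2 fold change (horizontal axis) of named genes (vertical axis, grouped by theme) in the libraries labelled siRNA1 (filled) and siRNA2 (open) against those labelled NTC. Bars give the standard error derived from the fold change and the edgeR F statistic (3 libraries per group). IL7R stands at −1.33 and CCR4 at 1.34 under the siRNA1 label, and no gene shown passed the test under the siRNA2 label.

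Receptor and signalling lists held members that moved both ways. Of 29 genes of the T cell receptor complex and its proximal signalling, the kinase PRKCQ (log2 fold change 0.77) and the phosphatase PTPRC (0.57) rose and CD3G (−0.44) fell, with 3 higher and 1 lower adjusted over the list alone and 8 and 4 under the block. Camera gave the list an adjusted p of 0.157. Of 29 T cell transcription factors, RUNX3 rose (0.61) and BACH2 (−0.62) and MYB fell, with 3 higher and 6 lower adjusted over the list alone and 6 and 8 under the block (camera adjusted p = 0.233). Of 29 integrins and migration receptors, CXCR3, CCR4 and ITGB7 (0.96) rose, while CCR8 (−0.95) and ITGA6 (−0.75) fell, with 4 higher and 3 lower adjusted over the list alone and 6 each way under the block. Camera gave it an adjusted p of 0.793, while the list's median was −0.03 and its mean 0.07. Of 26 JAK-STAT cytokine signalling genes, IL2RB rose and IL7R and IL10RB (−0.50) fell, with 5 higher and 2 lower adjusted over the list alone and 5 and 3 under the block (camera adjusted p = 0.429). Of 13 genes of the RNA interference machinery AGO4 fell (−0.49), of 23 immediate-early genes KLF10 rose (0.56), of 7 MHC class II genes HLA-DMB rose, and of 9 B cell markers IGLL1 fell, each also the only call adjusted over the list alone (camera adjusted p = 0.144, 0.157, 0.233 and 0.0968). Under the block 0, 5, 1 and 1 of these lists' members were higher and 3, 1, 0 and 2 lower. Fry's mixed test, which counts changes in either direction, gave adjusted p of 7.03e-08 for T cell receptor genes and 7.03e-08 for T cell transcription factors. It gave 3.11e-10 for integrins and migration receptors, 5e-06 for JAK-STAT genes and 5.31e-06 for RNA interference machinery. For immediate-early genes, MHC class II genes and B cell markers it gave 0.323, 0.000771 and 0.0106. Among the 9 fits with 1 library left out, edgeR lost the call of BACH2 in 8 (highest adjusted p = 0.175), NKG7 in 7 (0.157), RUNX3 in 6 (0.161), CD3G in 5 (0.0923), IL10RB in 5 (0.0806), ITGB7 in 4 (0.112), KLF10 in 4 (0.149), UHRF1 in 3 (0.0852), CCR8 in 2 (0.055), HLA-DMB in 2 (0.0613) and DNTT in 1 (0.0613).

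The remaining lists had no member past the test over all genes without the block. Adjusted over the list alone, 1 of 19 T-ALL tumour suppressors fell (camera adjusted p = 0.157), 2 of 29 genes of ATF4 and the unfolded protein response rose (0.413), 3 of 15 NF-kappa-B targets rose and 2 fell (0.0631), and 1 of 3 epithelial and fibroblast markers rose (0.636). Adjusted over the list alone, no member passed among 48 G2/M phase genes (camera adjusted p = 0.0543), 16 spindle checkpoint genes (0.6), 39 interferon-stimulated genes (0.144), 22 p53 target genes (0.609), 15 BCL2 family genes (0.641), 23 cholesterol synthesis genes (0.6), 29 glycolysis and hypoxia genes (0.144), 76 ribosomal protein genes (0.0805), 13 mitochondrially encoded genes (0.233), 14 MHC class I genes (0.818), 7 GIMAP genes (0.233), 5 myeloid cell markers (0.498), 3 erythroid and megakaryocyte markers (0.6) and 25 lncRNAs linked to T-ALL or to growth (0.636). With the replicate block members of most of these lists passed over all genes. Higher and lower were 8 and 3 NF-kappa-B targets, 9 and 4 interferon-stimulated genes, 10 and 1 G2/M phase genes, 6 and 1 genes of ATF4 and the unfolded protein response, and 4 and 1 glycolysis and hypoxia genes. They were 2 and 5 T-ALL tumour suppressors, 4 and 0 spindle checkpoint genes, 1 and 4 lncRNAs linked to T-ALL or to growth, 1 and 2 p53 target genes, 2 and 1 BCL2 family genes and 1 and 2 MHC class I genes. Among ribosomal protein genes 2 were lower, and 1 each among cholesterol synthesis genes, GIMAP genes, myeloid cell markers and epithelial and fibroblast markers. With the block camera also called G2/M phase genes (adjusted p = 6.76e-05), glycolysis and hypoxia genes (0.0221), mitochondrially encoded genes (0.037) and NF-kappa-B targets (0.0229) as higher. It called ribosomal protein genes (0.0283), GIMAP genes (0.036), B cell markers (0.0103) and T-ALL transcription factor oncogenes (0.029) as lower, and none of these calls held with an estimated correlation (adjusted p = 0.537 for GIMAP genes, 0.55 for G2/M phase genes). Of 3360 lncRNA genes, 7 rose and 12 fell, and with the replicate block 158 rose and 87 fell. Among those that passed without it were EPHA1-AS1 (1.21), TNRC6C-AS1 (0.91), AC020916.1 (0.80) and LINC01138 (0.61), and AC011893.1 (−1.32), AC022167.3 (−1.31), LINC01120 (−1.25), AP000345.2 (−1.16) and HHIP-AS1 (−1.07), as log2 fold changes. Of these, LINC01120, AC011893.1 and HHIP-AS1 passed in all 9 fits with 1 library left out, and edgeR lost LINC01138 in 7 (highest adjusted p = 0.179), TNRC6C-AS1 in 5 (0.112), AC020916.1 in 5 (0.119), AP000345.2 in 5 (0.141), AC022167.3 in 4 (0.0979) and EPHA1-AS1 in 3 (0.0852).

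The second single comparison asks the same of TLX1 siRNA2. Without the replicate block, no single gene passed in the libraries labelled siRNA2 against those labelled NTC. Camera placed cholesterol synthesis and ribosomal protein genes low as lists. Neither held with an estimated correlation (adjusted p = 0.329 and 0.57 with an estimated correlation) or under fry (adjusted p = 0.641 and 0.835). By edgeR quasi-likelihood 0 of 18554 genes passed, with 392 at an unadjusted p under 0.05. By other tools, limma-voom called 0, DESeq2 4, and edgeR with the replicate number as a block 28 (16 higher, 12 lower). Cholesterol synthesis genes had a median log2 fold change of −0.19 over 23 members (camera adjusted p = 7.71e-11; adjusted p = 0.329 with an estimated correlation), with 0 members passing over the list alone. With the block 0 were lower over all genes and 14 over the list alone. Ribosomal protein genes had a median of −0.10 over 76 members (camera adjusted p = 4.61e-13; adjusted p = 0.57 with an estimated correlation), with 0 passing over the list alone, and with the block 1 lower over all genes, RPL37, and 5 over the list alone. The 7 GIMAP genes, GTPases of lymphocytes, had a median of −0.21 (camera adjusted p = 0.00214; adjusted p = 0.57 with an estimated correlation), with 0 passing over the list alone, and with the block 0 lower over all genes and 6 over the list alone. The 9 B cell markers had a median of −0.27 (camera adjusted p = 0.0214; adjusted p = 0.329 with an estimated correlation), with 0 passing over the list alone, and with the block 0 lower over all genes and 4 over the list alone. The replicate block added thymocyte stage markers (camera adjusted p = 0.0402; adjusted p = 0.6 with an estimated correlation) and G1/S phase genes (0.00385; adjusted p = 0.752 with an estimated correlation) to these 4 lists, all lower. The GIMAP call was lost without NTC replicate 1 (camera adjusted p = 0.224) or siRNA2 replicate 2 (0.62) and the B cell call without NTC replicate 1 (0.336), siRNA2 replicate 2 (0.0734) or siRNA2 replicate 3 (0.124). In all 8 lists were called without NTC replicate 2 and 7 without NTC replicate 3.

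The main comparison weights both TLX1 siRNA groups equally against NTC. By label, 3 genes passed: TLX1 rose 1.63-fold (log2 fold change 0.71, SE 0.09, edgeR quasi-likelihood adjusted p = 0.0385), and DAB2IP (−1.57) and ADGRG1 (−1.13) fell, both with an edgeR adjusted p of 0.00343. The rise of TLX1 again goes against the labels, and it came from the libraries labelled siRNA1. Without the block, neither DAB2IP (−0.36) nor ADGRG1 (−0.47) passed under the siRNA2 label alone, as log2 fold changes. The 5 genes with the lowest adjusted p in each direction include these 3 and 7 that did not pass by edgeR. Log2 fold changes were 0.64 for MAP3K8, 0.83 for GPR65, −0.47 for MZB1, −0.92 for TSHR and −0.84 for LINC01120, each with an edgeR adjusted p of 0.0558. They were 1.14 for CYB561 (edgeR adjusted p = 0.0635) and 1.30 for SNAI2 (edgeR adjusted p = 0.0988). With the replicate block all 7 passed by edgeR, with adjusted p of 3.54e-06 for MAP3K8, 1.28e-05 for GPR65, 1.43e-05 for MZB1, 7.58e-10 for TSHR, 6.7e-06 for LINC01120, 0.000688 for CYB561 and 4.89e-06 for SNAI2. At an unadjusted p under 0.05 there were 970 genes, DESeq2 called 110 and limma-voom 3. With the replicate number as a block, edgeR called 728 genes (314 higher, 414 lower), TLX1 among them (adjusted p = 8.78e-07). Among lncRNA genes edgeR called 0, limma-voom 0, DESeq2 11 and the block 60 (32 higher, 28 lower). The TLX1 call was lost without NTC replicates 1 (adjusted p = 0.0797), 2 (0.219) or 3 (0.177), without siRNA1 replicate 3 (0.0614) or siRNA2 replicate 1 (0.0734), by edgeR. It was lost without the 3 replicate 1 libraries (0.17), which also ended the call of DAB2IP (0.0976). The count of 3 became 6 without NTC replicate 1, 7 and 6 without siRNA1 replicates 1 and 2, 5 without siRNA2 replicate 2 and 1 without the 3 replicate 1 libraries. For lncRNA genes, 1 passed without siRNA1 replicate 2.

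As lists, camera placed 8 lower and 1 higher in this combined comparison. No list had a member past the test over all genes except under the block. Without the block, none of these lists was called under both labels separately. Under the siRNA2 label camera gave adjusted p of 0.271 for NOTCH1 targets, 0.408 for thymocyte, 0.691 for MYC, 0.253 for G1/S and 0.955 for NK genes. Under the siRNA1 label it gave 0.6 for cholesterol, 0.0805 for ribosomal, 0.233 for GIMAP and 0.0968 for B cell genes. The lower lists were NOTCH1 targets (adjusted p = 4.15e-05; adjusted p = 0.148 with an estimated correlation), thymocyte stage markers (0.000643; adjusted p = 0.591 with an estimated correlation), MYC and nucleolar genes (0.00106; adjusted p = 0.626 with an estimated correlation) and cholesterol synthesis genes (0.00106; adjusted p = 0.591 with an estimated correlation). Ribosomal protein genes (6.7e-06; adjusted p = 0.61 with an estimated correlation), GIMAP genes (0.0187; adjusted p = 0.61 with an estimated correlation), B cell markers (0.0118; adjusted p = 0.255 with an estimated correlation) and G1/S phase genes (0.0196; adjusted p = 0.742 with an estimated correlation) were also lower. NK and cytotoxic cell markers were higher (0.0187; adjusted p = 0.255 with an estimated correlation). Adjusted over the list alone, 3 thymocyte markers, 2 NOTCH1 targets, 1 MYC and nucleolar gene and 1 B cell marker were lower and 1 cytotoxic marker was higher. Under the block 12, 6, 5, 3 and 2 passed over all genes. So did 3 cholesterol synthesis, 2 ribosomal protein and 1 GIMAP gene, all lower, and 1 higher and 1 lower G1/S phase gene. Fry called 0 lists, and with the block 3 (thymocyte markers and NOTCH1 targets, adjusted p = 0.0207 each, and GIMAP genes, 0.0327). The block added G2/M phase genes (0.0201; adjusted p = 0.649 with an estimated correlation) and glycolysis and hypoxia genes (0.0161; adjusted p = 0.624 with an estimated correlation) to the camera calls. Without NTC replicate 3 the thymocyte (0.146), cholesterol (0.279), ribosomal (0.0985), GIMAP (0.0985) and G1/S (0.398) calls were lost, and camera called 5 lists, of which 4 were among the 9. The MYC (0.123) and NK (0.103) calls were lost without NTC replicate 2, and without NTC replicate 1 the GIMAP (0.345), B cell (0.238) and G1/S (0.364) calls, G1/S in the other direction. Without siRNA1 replicate 2 camera called 5 lists, with the GIMAP (0.147), NK (0.053), B cell (0.053) and G1/S (0.448) calls lost. GIMAP (0.275), NK (0.0598) and G1/S (0.658) were lost without siRNA2 replicate 2, and G1/S without siRNA1 replicate 3 (0.0555).

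A further comparison asks which genes differed the same way under both TLX1 siRNA labels. By edgeR quasi-likelihood 0 genes passed in both, since 0 passed under the siRNA2 label (392 at an unadjusted p under 0.05). Limma-voom also called 0, DESeq2 called 1 and the replicate block 12. Under the block 10 genes rose in both, among them RGS1, a regulator of G protein signalling (log2 fold changes 0.72 and 0.85 for siRNA1 and siRNA2), PDE4D, a cAMP phosphodiesterase (0.79 and 0.84), SYTL3 (0.91 and 0.91), the glucose transporter gene SLC2A3 (0.82 and 0.75) and UNG, a uracil-DNA glycosylase (0.54 and 0.79). The 2 that fell were LBH (−1.09 and −0.34) and ADGRG1 (−1.78 and −0.46). Both comparisons use the same NTC libraries, so values correlate even in unchanged groups. Across genes, which are not independent replicates, the fold changes correlated with r = 0.405, against 0.502 (0.476 to 0.517) in 20 simulations of unchanged groups. The covariance was 0.0273 against 0.0202 in the simulations, a difference of 0.00708, and 61.9% of genes had the same sign against 66.7%. At an unadjusted edgeR p under 0.05 in both, without the block, 109 genes went the same way and 2 opposite ways. The simulations gave 9.7 the same way and independent lists would give 20.0. Independent lists would share 0.876 higher and 0.712 lower calls under the block, and the simulations shared 0. The 3 NTC libraries cannot be split into parts of at least 2, so part of any excess may come from the shared controls.

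**Figure D3:**
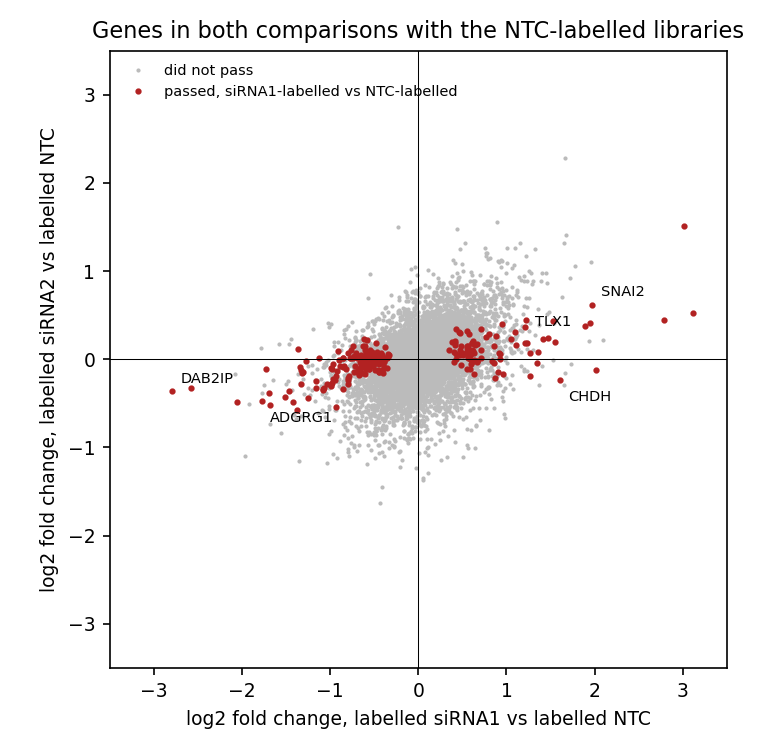
Log2 fold change against the NTC-labelled libraries of 18530 tested genes (Y-linked genes and XIST not drawn) under the siRNA1 label (horizontal axis) and the siRNA2 label (vertical axis), with genes past the edgeR test under the siRNA1 label coloured. DAB2IP stands at −2.79 and TLX1 at 1.23 on the horizontal axis, and 0 genes passed on the vertical axis without the replicate block.

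The last comparison tests the difference between the TLX1 siRNA groups directly. By label, many but not all genes that passed between siRNA1 and NTC also passed between siRNA1 and siRNA2. DAB2IP (log2 fold change −2.43), TC2N (−2.25), TSHR (−1.62), TERT (−1.48), ADGRG1 (−1.31) and IL7R (−1.21) were lower under the siRNA1 label. In turn CHDH (1.84), CXCR3 (1.54), CYB561 (1.51), GOLGA7B (1.45), CCR4 (1.39) and SNAI2 (1.35) were higher under the siRNA1 label than under the siRNA2 label. Named genes that passed against NTC but not here by edgeR included WNK2 (adjusted p = 0.0777), EPHA1-AS1 (0.0905), RUNX3 (0.164), PTPRU (0.201) and DEFA8P (0.202), all of which passed here with the replicate block. All 45 named genes that passed had their 3 libraries on one side of the other 3. They were chosen for passing on these libraries, so this is no further evidence, and chance gives such a split to 10% of unselected genes. By edgeR quasi-likelihood 201 genes passed (64 higher, 137 lower), 5 and 6 of them lncRNA genes, and with the replicate block 1958 (981 higher, 977 lower), 143 and 73 of them lncRNA genes. Of these and the 238 genes of the comparison of siRNA1 with NTC, 50 were higher in both and 111 lower in both, with 0 in opposite directions. Independent lists would share 0.300 and 1.11 and simulated unchanged groups against the shared siRNA1 libraries shared 0. Across genes the correlation of these fold changes was 0.710 against 0.464 in the simulations, the covariance 0.0621 against 0.0183, a difference of 0.0438, and 76.0% of genes had the same sign against 66.0%. The siRNA1 libraries cannot be split into parts of at least 2 either, so part of the excess may come from sharing them. The count of 201 was 125 without NTC replicate 3 and 78, 105 and 72 without siRNA1 replicates 1, 2 and 3. It was 79, 121 and 106 without siRNA2 replicates 1, 2 and 3, and 33 without the 3 replicate 1 libraries. Of the 45 named calls 16 held with any 1 library left out, TLX1, DAB2IP, TC2N, TSHR, TERT, ADGRG1, IL7R, CCR4, GOLGA7B and CYB561 among them. Of the others 3, 5 and 10 were lost without NTC replicates 1, 2 and 3, 25, 18 and 24 without siRNA1 replicates 1, 2 and 3, and 23, 13 and 17 without siRNA2 replicates 1, 2 and 3.

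Of the lists, camera called 10 of 32 between the siRNA labels, 5 higher and 5 lower under siRNA1. Of 14 NOTCH1 targets 2 fell, IL7R and NOTCH3, with 5 adjusted over the list alone and 6 under the block (camera adjusted p = 0.000201; adjusted p = 0.107 with an estimated correlation). Of 25 thymocyte markers 3 fell, with 6 lower and 2 higher adjusted over the list alone and 14 and 3 under the block (0.00123; adjusted p = 0.377 with an estimated correlation). MYC and nucleolar genes (1 of 34 fell, 1 adjusted over the list alone, 7 under the block, 8.9e-05; adjusted p = 0.638 with an estimated correlation) were lower, as were T-ALL tumour suppressors (0 of 19, 1 adjusted over the list alone, 5 under the block, 0.0234; adjusted p = 0.273 with an estimated correlation). In the RNA interference machinery 2 of 13 fell, AGO4 (log2 fold change −0.54) and AGO2 (−0.47), Argonaute proteins that bind small RNAs, with 3 lower and 1 higher adjusted over the list alone and 4 and 1 under the block (0.00302; adjusted p = 0.371 with an estimated correlation). NK and cytotoxic markers were higher as a list (2 of 12 rose, 3 adjusted over the list alone, 4 under the block, 0.000956; adjusted p = 0.107 with an estimated correlation). Cholesterol synthesis genes (0 of 23, 0 adjusted over the list alone, 6 under the block, 0.000615; adjusted p = 0.371 with an estimated correlation) and G2/M phase genes (0 of 48, 0 adjusted over the list alone, 16 higher and 1 lower under the block, 0.00847; adjusted p = 0.824 with an estimated correlation) were higher. So were ribosomal protein genes (1 of 76, RPL37 at 0.43, 1 adjusted over the list alone, 1 under the block, 0.00968; adjusted p = 0.824 with an estimated correlation) and interferon-stimulated genes (1 of 39, RSAD2 at 0.85, 2 adjusted over the list alone, 11 higher and 3 lower under the block, 0.0299; adjusted p = 0.371 with an estimated correlation). Fry called 3 lists, NOTCH1 targets and tumour suppressors (adjusted p = 0.0358 each) and NK markers (0.014), and with the block 6. Camera with the block called 12, adding mitochondrially encoded genes (0.0255; adjusted p = 0.694 with an estimated correlation) and NF-kappa-B targets (0.031; adjusted p = 0.524 with an estimated correlation). With 1 library left out, the call of tumour suppressors was lost (camera adjusted p = 0.0869 without siRNA1 replicate 3, 0.0705 without siRNA2 replicate 2). So was that of G2/M genes (0.978 without siRNA1 replicate 2, 0.403 and 0.155 without siRNA2 replicates 1 and 3). Interferon-stimulated genes were lost too (0.144 without siRNA1 replicate 1, 0.118 without siRNA2 replicate 2). The same held for MYC genes (camera adjusted p = 0.164 without siRNA2 replicate 2) and ribosomal genes (0.178 without siRNA1 replicate 2, 0.961 without siRNA2 replicate 1).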

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

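Of the tests in this part, those of a TLX1-directed siRNA that raised its target, of depth and composition, and of 3′ UTR length and base composition were chosen after the result was seen.

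The effects of the TLX1 siRNA labels differed from each other when tested directly, by edgeR quasi-likelihood with Benjamini-Hochberg adjustment: 201 genes passed, and of 59 named genes tested 45 passed, 22 higher and 23 lower under the siRNA1 label. As log2 fold changes of siRNA1 over siRNA2, TLX1 stood at 1.04, CHDH at 1.84, CXCR3 at 1.54, CYB561 at 1.51, GOLGA7B at 1.45, CCR4 at 1.39, CASP17P at 1.37, NCR2 at 1.36, SNAI2 at 1.35, GBP2 at 1.27, RXRA at 1.22, LINC002481 at 1.20, HLA-DMB at 1.19, ITGB7 at 1.13, MAP3K8 at 0.95, RSAD2 at 0.85, TNRC6C-AS1 at 0.84, GPR65 at 0.78, IL2RB at 0.61, PTPRC at 0.55, NKG7 at 0.54 and RPL37 at 0.43. On the lower side were DAB2IP at −2.43, TC2N at −2.25, TSHR at −1.62, TERT at −1.48, IGLL1 at −1.31, ADGRG1 at −1.31, IL7R at −1.21, AC011893.1 at −1.16, AC022167.3 at −1.16, DIP2C at −1.11, DNTT at −1.06, ARPP21 at −0.89, ITGA6 at −0.89, LINC01120 at −0.81, BACH2 at −0.78, MZB1 at −0.71, NOTCH3 at −0.55, AGO4 at −0.54, ODC1 at −0.52, IL10RB at −0.51, MYB at −0.50, AGO2 at −0.47 and CD3G at −0.43.

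TLX1 was higher in the libraries labelled siRNA1 than in those labelled NTC, against the labels. Depth or composition of the libraries is argued against as the whole cause, since the lowest log2 fold change of TLX1 over all alternatives was 1.12. An siRNA directed at TLX1 that raised its mRNA stays open. The 3′ UTR word of the genes lowered in the libraries labelled siRNA1 occurred in 0 of 5 annotated TLX1 transcripts on either strand. If the word marks the seed of that siRNA, its absence argues against TLX1 as the target, since such an siRNA would match TLX1 mRNA. Whether the word marks that seed is not known, and most words are absent from the longest TLX1 transcript by chance. An exchange of the labels NTC and siRNA1 is a candidate explanation: the word of the libraries labelled NTC (AATCACT, z −8.20, limit −4.39) occurred in TLX1 mRNA (2 of 5 transcripts) and that of the libraries labelled siRNA1 did not, a difference of 1 that was predicted for an exchange, and TLX1 would then be 2.34-fold and 2.05-fold lower with the TLX1 siRNAs than in the control. It stays a hypothesis, because 15% of all words occur in the longest TLX1 transcript by chance, the word ranked first in replicates 2 and 3 but 573rd in replicate 1, and of the overlapping words ranked 2 and 3 under the NTC label, both past the limit, ATCACTA (z −6.97) occurred in 2 of 5 TLX1 transcripts and TAATCAC (z −5.14) in 0. Also, the libraries labelled siRNA2 had no word past the limit (GACGCTA, z −4.33, limit −4.56), and the siRNA sequences were not known here. If the labels were exchanged, the count of 0 genes passing the same way under both siRNA labels would not measure what the TLX1 siRNAs share. The comparisons of the siRNA1 label with the NTC and siRNA2 labels would come closer to it. They would also hold any effect of the siRNA in the libraries labelled siRNA1 that is unrelated to TLX1. Of the lower genes searched, 33.3% held GCAGTAC against NTC and 37.9% against siRNA2, and of the other genes 4.12% and 4.06%. In both comparisons 50 genes were higher and 111 lower under the siRNA1 label, though these comparisons share the siRNA1 libraries.

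Genes with the word GCAGTAC in their 3′ UTRs (437 of 9722 searched) lay lower in the libraries labelled siRNA1 (z −14.1, limit −4.35). The word ranked first in each replicate number. Of the 126 searched genes that passed as lower against NTC, 42 (33.3%) held it. Length and base composition of 3′ UTRs are argued against as the whole cause. The z was −16.8 before and −14.1 after both and expression were regressed out. Pairing of the seed of a transfected siRNA strand with mRNAs that hold the word may be the cause. The 143 genes with the word followed by A lay lower (mean −0.19) than the 294 with the word alone (−0.09). The difference was −0.10 (one-sided permutation p = 6e-05, 100000 resamples), as predicted beforehand. Under this hypothesis part of the differences is an off-target effect of 1 siRNA, whichever siRNA the libraries hold. Among named genes that were searched, IL10RB and AGO4 (lower) and CHDH (higher) had the word. Most did not, DAB2IP, TSHR, TERT, ADGRG1, IL7R, DNTT and NOTCH3 (all lower) among them. Only the 3′ UTR of 1 transcript per gene was searched. Under the siRNA1 label CAGTACA (z −9.02) and GCAATAC (z −5.21) were also past the limit, and named genes were not checked for these words. Some named genes, such as TC2N, were not searched. Whether any of the other differences follow from TLX1 was not tested, because no sample gives the siRNA without TLX1 as its target.

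Other splits of the same libraries were counted for each comparison. For siRNA1 against NTC and siRNA1 against siRNA2, 1 of 10 splits called as many genes, the real split itself. It called 238 and 201 genes, against 0 in the highest other split. For siRNA2 against NTC 10 of 10 called as many, with 0 genes in each. A total of 10 splits is too few for a share under 0.05. With the replicate block the real splits called 2117, 1958 and 28 genes in the same order. The 3 other splits that part all pairs called 0 with the block, again too few for such a share. For both TLX1 siRNAs against NTC, 5 of 100 drawn splits (of 840 possible) called at least the real 3 genes, the real split among them. The others largely follow groups or replicate numbers, so this share cannot decide whether chance gave the 3 genes. The highest other split called 489, and it set the libraries labelled siRNA1 against the other 6, which points to a structure of the samples. Splits that set the replicate 3 libraries of all groups against the rest called 85 and 100. A split with replicate 2 labelled NTC and siRNA2 and replicate 3 labelled siRNA1 on one side called 26. The 13 drawn splits that part all pairs by replicate number, as the real one does, called at most 1. For lncRNA genes and for genes changed the same way under both labels, the real count was 0, which 100 of 100 splits reach by construction, so these counts test nothing; the highest other splits gave 44 and 194.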

How the results depend on the processing

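The fit without the 3 replicate 1 libraries, the lists with library size alone, and the block with an estimated correlation or fry were chosen after the result was seen; the cause was not tested except where stated. The log2 fold change of TLX1 for siRNA1 against NTC and against siRNA2 passed in every alternative, and for siRNA2 against NTC it passed in none. For both siRNAs against NTC it was lost with the strand sum (0.65, adjusted p = 0.0609) and without the replicate 1 libraries (0.75, adjusted p = 0.17), and with 1 library left out it ranged from 0.66 to 0.75 (edgeR adjusted p 0.0295 to 0.219). Counts of genes are given in the order both siRNAs against NTC, siRNA1 against NTC, siRNA2 against NTC, siRNA1 against siRNA2. Without a filter they were 169, 590, 15 and 557, with DESeq2 110, 553, 4 and 522, and with the replicate block 728, 2117, 28 and 1958, which include all 238 and 201 genes of the unblocked fit. Without the replicate 1 libraries, where fewer libraries were tested, 1, 75 and 33 passed for the first, second and last comparison, and the stricter thresholds gave 144 and 115 (1.5-fold) and 89 and 49 (adjusted p under 0.01) for the second and last. With only the groups compared the last had 117. With 1 library left out the ranges were 2 to 7, 103 to 253, 0 to 0 and 72 to 185. LncRNA genes in the first comparison numbered 12 without a filter, 11 with DESeq2, 60 with the block and 0 to 1 with 1 library left out, and genes passing the same way under both siRNA labels 11, 1, 12 and 0 to 0.

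Lists called by camera with an estimated correlation numbered 0, with or without the block, in all 4 comparisons. Fry called 0, 3, 0 and 3, and with the block 3, 9, 0 and 6. For siRNA1 against NTC camera called 13 with the block, 8 with library size alone and 8 without the replicate 1 libraries. With 1 library left out camera called 5 to 10, 4 to 9, 3 to 8 and 8 to 12 lists. The direction of the G1/S phase genes turned without NTC replicate 1, for both siRNAs against NTC (camera adjusted p = 0.364, from 2.55e-13 to 0.658 over the left-out libraries) and for siRNA1 against NTC (0.859, from 1.14e-09 to 0.859). Over all named genes and alternatives, 3841 results stayed on their side of the threshold, 320 were no longer past it and 178 came past it. Of the 3841, 60 turned direction, past the threshold in neither fit, and 0 turned among results past it in either. RLE factors and limma-voom moved no count of genes by more than 1.5 times. Among named genes and lists the block lost no call; it brought 69 further named-gene results past the threshold, of which only part are given beside the results. A fit of only the groups compared does not exist for the combined comparison, which uses all 3 groups. Depth limits little here except for transcripts of a few counts, such as TLX2.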

Other observations

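The tests of RNA from another T-lineage source and of deeper sequencing of the replicate 1 libraries were chosen after the result was seen.

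With the replicate number as a block, SHMT1, GSTP1, U2AF2 and EZR fell and EPAS1 and GINM1 rose in the libraries labelled siRNA2 against those labelled NTC. SHMT1, the cytosolic serine hydroxymethyltransferase, had a log2 fold change of −0.69 (SE 0.07, edgeR quasi-likelihood adjusted p = 1.97e-05, n = 3 per group), GSTP1, a glutathione transferase, −0.50 (edgeR adjusted p = 0.000951), the splicing factor U2AF2 −0.49 (edgeR adjusted p = 0.000674) and the cytoskeletal linker EZR −0.41 (edgeR adjusted p = 0.00258). EPAS1, a hypoxia-inducible transcription factor, rose by 0.86 (edgeR adjusted p = 0.00295) and GINM1 by 0.44 (edgeR adjusted p = 0.00263). None of these 6 passed without the block, where the adjusted p was 1 for SHMT1, EZR, EPAS1 and GINM1, 0.74 for GSTP1 and 0.407 for U2AF2. In the libraries labelled siRNA1 their blocked log2 fold changes against NTC were 0.05, −0.09, −0.17, 0.00, 0.11 and 0.09 in the order SHMT1, GSTP1, U2AF2, EZR, EPAS1 and GINM1, none past the test.

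A group of transcripts was seen in the replicate 1 libraries of every group and hardly in the others. By the rule tried first, with a floor of 3 counts in each library, there were 6: H1F0 (216, 470 and 220 counts in the replicate 1 libraries labelled NTC, siRNA1 and siRNA2), NLGN4X (89, 117, 79), CDKN2A (62, 93, 60), RORB (50, 64, 57), TLX3 (33, 54, 41) and ANKRD33B (30, 52, 36), while replicates 2 and 3 had 0 such transcripts. CDKN2A and TLX3 had 0 counts in all 6 other libraries, so CDKN2A was at least 143-fold and TLX3 at least 85.9-fold higher, against a floor of 3 counts over those libraries together. Deeper sequencing is argued against, since the mean depth of the replicate 1 libraries was 0.910 times that of the others. RNA of another T-lineage cell source may be present, but this cannot be told apart from other causes: by the rule tried first 0 of the 6 transcripts were T cell receptor segments (0.0123 by chance, exact hypergeometric p = 1), and too few transcripts passed to decide. After that result the floor was changed to 3 counts over the pooled libraries, and 19 transcripts passed, of which 2 were receptor segments, TRBV6-2 (11, 31 and 17 counts) and TRBJ1-6 (11, 14 and 10), where 0.0391 fall by chance (exact hypergeometric p = 0.000686); because the rule was changed after the first gave 0, this p is no test.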
